A study of Mus musculus with 3 samples.

How the data were processed

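Blood cells of C57BL/6J mice were sequenced as 3 droplet libraries, 1 for each of the groups Sham, CLP and HDCA+CLP. Per the labels' protocols, blood was digested with hyaluronidase and DNase I, libraries were made with 10x Chromium 3′ v3 chemistry, and reads were paired and 150 bp long. The number of animals behind each library is not given in the sources used here. The deposited files hold raw UMI counts per gene and cell barcode, which per the file headers came from Cell Ranger 5.0.1; the submitters' processing notes also name Seurat 4.0.6, R 4.0.3 and a mouse genome build, but no deposited file holds the authors' clusters or cell types. The matrices have 31053 genes, of which 30934 gene IDs were matched to the reference annotation; no coordinates were used. The barcodes were already filtered by the authors' pipeline, with 500 to 502 UMIs in the smallest of each library. Totals were 7159 barcodes and 42427093 UMIs in Sham, 11387 and 87031721 in CLP, and 12205 and 95178381 in HDCA+CLP.

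Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% of UMIs from mitochondrially encoded genes. The mitochondrial limit removed 261 Sham, 542 CLP and 166 HDCA+CLP barcodes, and 6891, 10840 and 12023 passed all filters. Doublets were scored within each library against 2 simulated doublets per cell, and the highest-scoring cells were left out at 0.8% of the library per 1000 barcodes, which removed 395 (5.73%), 987 (9.11%) and 1174 (9.76%). Of the cells removed this way, 52.2%, 30.8% and 24.4% had at least 3 marker UMIs of each of 2 classes, against 0.77%, 2.47% and 2.19% of those kept. Only some pairs of classes were counted. Neutrophil with monocyte, T cell with NK cell and NK cell with monocyte were left out, so doublets of these pairs went unchecked. The 27198 kept cells of the 3 libraries were clustered together without batch correction: 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 gave 26 clusters. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

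Clusters were named from 16 marker sets written before the data were examined. A marker counted when it was found in at least 10% of the cluster's cells and was at least 2-fold above the median of the clusters, with 10 CPM added to both. A class needed at least 3 such markers and 25% of its list. A cluster was left unnamed when its 10 highest genes held more markers of another class, or when a second class exceeded 95% of the best class's share of markers, or 80% with as many markers among those 10 genes. These thresholds were set after the clusters were seen. Cluster 21, with neutrophil and monocyte markers and few UMIs per cell, and cluster 25, with platelet and neutrophil markers, stayed unnamed. Classes with at least 200 cells in each library were compared, which left 5. Neutrophil-like cells numbered 245 in Sham, 4459 in CLP and 8166 in HDCA+CLP, monocyte-like cells 290, 741 and 323, B cell-like cells 2639, 345 and 295, T cell-like cells 3016, 3011 and 1405, and NK cell-like cells 279, 1113 and 557. Median UMIs per neutrophil-like cell were 4120, 8427 and 7880 in the same order.

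UMIs were summed over the cells of a class and library and scaled to a total of 1000000 (CPM). Intervals of CPM are exact Poisson intervals, those of ratios come from the exact conditional binomial interval, those of shares are exact Clopper-Pearson intervals, and those of list medians in the plot come from 1000 resamples of the counts. All are 95% intervals for counting error, and differences between cells, animals or preparations are outside them. A gene at 0 in 1 library was set against a floor of 3 counts. A fold over this floor is a single value, not a bound of an interval. Because 1 library stands for each group, no test between groups, no p-value and no count of changed genes was made from cells.

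Genes to name were chosen by a rule fixed before the data were examined: in each class and comparison, the 3 with the largest difference in each direction among genes with at least 50 UMIs and 50 CPM, ranked by the bound of the interval nearest to 0. Left out were mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor, predicted, Y-linked and Xist genes, and genes whose level was under 20% of that in the class highest for them in the same library, since free RNA can supply these. Tlr4, Ly96, Cd14, Gpbar1 and Nr1h4 were fixed in advance. Examples from gene lists were among the 3 highest and 3 lowest members by the same bound, limited to those past the same free RNA limit, which was decided after the data were seen, and Malat1, AY036118 outside the classes where the rule names it, Ifng, Il10 in neutrophil-like cells, Elane, Mpo, Prtn3, Ifngr1 and Retnlg were chosen after their values were seen. The 25 gene lists were also written before the data were examined; members with at least 20 UMIs over both libraries were used, and a list needed at least 5. The reported results are 65 pairs of a list with a class and comparison: inflammatory response, Toll-like receptor 4 complex, type I interferon, interferon-gamma, granule proteins, sepsis-associated neutrophil genes, MHC class I and II, glucocorticoid response, glycolysis and hypoxia, oxidative phosphorylation, bile acid and oxysterol genes, naive state, activation, inhibitory receptors, cytotoxic effectors, trafficking, non-classical monocyte, cell cycle, immediate early and dissociation-associated, and mitochondrially encoded genes. They are a selection of the pairs computed, and the other pairs are not reported here. Dissociation-associated genes are linked to cell handling, and that list also holds the heat shock genes Hsph1 and Hspa8. Some list examples are not reported here. Each median was also placed among 10000 random lists matched for expression in 20 bins, and the percentile is a description of the list, not a test.

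Alternatives fixed in advance were limits of 5% and 20% mitochondrial UMIs, a minimum of 500 genes per cell, no doublet removal, a clustering resolution of 2, each library clustered alone, shares among cells other than neutrophil-like cells, median-of-ratios size factors, means over cells each scaled to its own total, and a minimum of 100 UMIs for list members. Lists without members under the free RNA limit, CLP against Sham without clusters of which at least 80% of cells came from CLP (15 and 23), and clusters weighted as in CLP (clusters with at least 50 cells in both libraries), were added after the data were seen. The weighting leaves out clusters 15 and 23 among others, and rests on cluster 13 alone in B cell-like, 9 in monocyte-like and 7 in NK cell-like cells.

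The ratios were tested on simulated data made from the class counts in 4 comparisons, each with 200 changed genes and 20 draws. Counts were drawn from Poisson distributions, the model behind the intervals, so coverage near 95% was built in. The draws check the computation only, since spread of counts between cells was not simulated. In neutrophil-like cells of CLP against Sham, intervals held the true value for 96.8% of unchanged genes and for 96.8%, 96.7% and 97.2% of genes changed 1.5-, 2- and 4-fold, and the direction was right for 87.3%, 94.2% and 98.9%. For HDCA+CLP against CLP in this class coverage was 95.7% for unchanged genes and 95.4%, 95.4% and 95.7% for changed ones, with the direction right for 97.5%, 99.6% and 100%. In B cell-like cells of CLP against Sham coverage was 96.3%, then 96.4%, 95.8% and 96.1%, with directions right for 95.0%, 98.7% and 97.0%, and for HDCA+CLP against CLP 96.2%, then 97.5%, 96.3% and 95.9%, with 94.9%, 99.0% and 100%. Lists of 20 genes changed 2-fold had medians of 0.90, 1.04, 0.88 and 0.91 in these comparisons. Protein levels, survival and other measurements of the study are not analysed here.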

Results

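Blood cells of C57BL/6J mice were profiled by droplet single-cell RNA sequencing in 3 libraries, 1 for each group and each labelled as taken at 12 h. The groups were labelled Sham, read here as sham surgery, CMC-treated with CLP (CLP), and HDCA-treated with CLP (HDCA+CLP). The Sham label names no CMC, so CLP against Sham may differ in CMC as well as in surgery. The labels give no order of treatment and surgery. CLP is read here as caecal ligation and puncture, a surgical model of sepsis, HDCA as hyodeoxycholic acid, a bile acid, and CMC as carboxymethylcellulose, since the labels leave the 3 abbreviations unexpanded. After the cell filters and the removal of called doublets, 6496 Sham, 9853 CLP and 10849 HDCA+CLP cells remained, with medians of 5238, 6514 and 7129 UMIs per cell. There were no replicates, so intervals are 95% intervals that cover counting error only and no test between groups was made. Classes were named from marker genes, and "like" marks a class named this way. Gene values are UMI counts scaled to 1000000 UMIs of a class and library (CPM), and ratios are on the log2 scale.

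Neutrophil-like cells were a far larger share of the CLP library than of the Sham library, and B cell-like cells a far smaller one. Neutrophil-like cells made up 3.77% (exact Clopper-Pearson interval 3.32 to 4.26) of Sham cells and 45.26% (44.27 to 46.24) of CLP cells, a 12.0-fold higher share. B cell-like cells were 40.62% (39.43 to 41.83) of Sham and 3.50% (3.15 to 3.88) of CLP cells, 11.6-fold lower. T cell-like cells were 46.43% (45.21 to 47.65) and 30.56% (29.65 to 31.48), NK cell-like cells 4.29% (3.81 to 4.82) and 11.3% (10.68 to 11.94), and monocyte-like cells 4.46% (3.97 to 5.0) and 7.52% (7.01 to 8.06). Among cells other than neutrophil-like cells, B cell-like cells were still lower in CLP (6.40% against 42.22%), NK cell-like cells were higher (20.63% against 4.46%), and the T cell-like share turned from lower to higher (55.82% against 48.25%). Clusters left without a class held 0.42%, 1.87% and 0.95% of Sham, CLP and HDCA+CLP cells. The labels call the cells mononuclear, and their protocol names no density gradient and no sort, so the neutrophil-like share also depends on what the preparation kept.

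**Figure D1:**
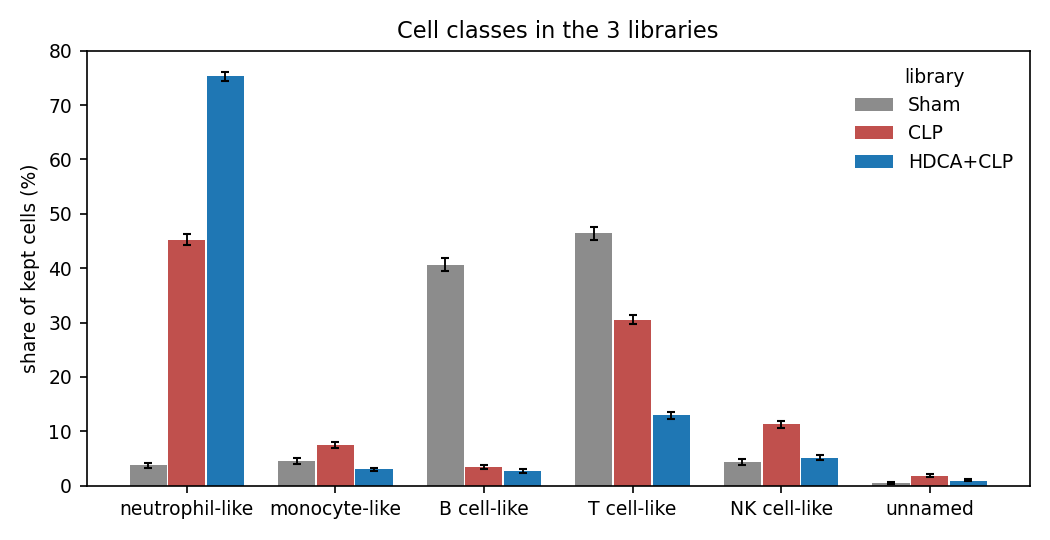
Shares of kept cells (%, vertical axis) in each cell class and library, with exact Clopper-Pearson 95% intervals. Neutrophil-like cells were 3.77% of Sham, 45.26% of CLP and 75.27% of HDCA+CLP cells, and B cell-like cells 40.62%, 3.50% and 2.72%.

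In neutrophil-like cells, granule protein and type I interferon response genes were higher in CLP than in Sham. Immediate early and dissociation-associated genes and the cytokine gene Il1b were lower. The classes rest on different clusters: cluster 22 held most Sham cells, and clusters 0, 1, 2, 6, 10 and 18 held those of CLP. Orm1, an acute phase glycoprotein, was at 19.6 CPM in Sham and 1018 in CLP (log2 ratio 5.70, 5.11 to 6.36; 7.09 as a mean over cells), and Mt1, a metal-binding metallothionein, at 6.82 and 165 (4.60, 3.62 to 5.81). Cpq, a peptidase, had 1 UMI in Sham against 87.9 CPM in CLP (6.69, 4.21 to 11.99; 7.56 as a mean over cells). Among the genes lower in CLP, Sirpb1c, a signal-regulatory protein, was at 163 and 0.652 CPM (-7.96, -8.63 to -7.36), Prr5l at 101 and 0.443 (-7.83), and Jaml, an adhesion molecule, at 335 and 1.93 (-7.44). Of 19 measured granule and immaturity genes 14 were higher, with a median log2 ratio of 1.16, such as Chil3 (3.38; 4.39 as a mean over cells), the antimicrobial Ngp (2.36; 3.43) and Camp (1.68; 2.79), whereas the surface marker Ly6g was lower (-0.72). Of 29 type I interferon response genes 27 were higher (median 1.24), Ifit1 (3.82), an inhibitor of viral translation, and the nucleic acid sensor Zbp1 (3.14) among them. MHC class I presentation genes were higher in 12 of 13 (median 0.61; Tap1 1.99, H2-K1 1.71), and nuclear genes of oxidative phosphorylation in 29 of 34 (0.64; Uqcrb 1.88). Immediate early and dissociation-associated genes were lower in all 16 measured (median -2.31), with Egr1 at -5.04 and Fos at -3.37. Cell handling was not tested as a source of this difference, and each group was 1 library. Glucocorticoid response genes were lower in 14 of 18 (median -1.16, and -0.55 with a minimum of 100 UMIs), with Dusp1, a phosphatase that limits MAP kinases, at -2.91 and Rgs2 at -2.96.

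The inflammatory genes downstream of Toll-like receptors and NF-kappaB did not move together in neutrophil-like cells. Tnf was at 6.82 CPM in Sham and 60.1 in CLP (3.14), and Nos2, the inducible nitric oxide synthase, had 3 UMIs against 25.1 CPM (3.29, 1.74 to 5.57), while Il1b was at 3089 and 161 CPM (-4.26) and the prostaglandin synthase Ptgs2 at 113 and 0.73 (-7.27; -6.45 as a mean over cells). Over 27 such genes 13 were higher and 14 lower, and their median of -0.10, at the percentile 80.08 among matched random lists, turned to 0.09 with size factors and 0.14 as a mean over cells. The Toll-like receptor 4 complex and adaptor list had 8 genes higher and 9 lower, with a median of -0.04 that was positive with size factors, although Irak3, an inhibitor of this signalling, was higher (1.22).

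Monocyte-like cells of CLP had higher inflammatory and interferon-gamma response genes than those of Sham, and lower genes of the non-classical, patrolling monocyte. Cluster 19 held most Sham cells and cluster 9 most CLP cells. Spp1 (osteopontin) had 3 UMIs in Sham against 527 CPM in CLP (9.09, 7.55 to 11.37). C1qb, a complement component, had 0 UMIs against 170 CPM, 176-fold higher over a floor of 3 counts. Sdc4, a syndecan, was at 1.61 and 532 CPM (8.37; 6.15 without doublet removal, 9.78 as a mean over cells). Hpgd, which breaks down prostaglandins, was at 348 CPM in Sham and 2.21 in CLP (-7.30), Ace at 235 and 4.5 (-5.71), and Cx3cr1, the fractalkine receptor of patrolling monocytes, at 283 and 7.89 (-5.17; -4.51 as a mean over cells). Of 30 inflammatory genes 23 were higher (median 2.20, at the percentile 100 among matched random lists). The monocyte attractant Ccl2 was at 10.9 and 655 CPM (5.91, or 3.77 without doublet removal). Acod1, the itaconate synthase, was 123-fold higher over the same floor, whereas Nfkb1 was lower (-0.67). Interferon-gamma response genes were higher in 14 of 15 (median 2.37), with Gbp5 at 3.51. The immunity GTPase Iigp1 was at 0 UMIs in Sham and 112-fold higher in CLP over that floor (log2 ratio 8.53 without doublet removal). Type I interferon response genes were higher in 28 of 31 (0.67; Ifit1 3.49, or 2.83 without doublet removal, and Isg15 2.61). Non-classical monocyte genes were lower in 11 of 12 (-2.30; Eno3 -4.95). Glycolysis and hypoxia genes were higher in 17 of 21 (0.62; Pfkfb3 2.06, Ldha 1.11), although the hexokinase gene Hk2 was lower (-1.56).

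Cell cycle genes were higher in all 18 measured in monocyte-like cells, with a median of 4.04 that was 1.18 at a clustering resolution of 2. The survivin gene Birc5 was at 5.99 and 3.58 in turn. At resolution 2, 607 rather than 741 CLP cells were named monocyte-like, and 4611 rather than 4459 neutrophil-like. Much of the cell cycle difference thus lay in cells whose class name depended on the resolution. MHC class II genes were mixed, with 6 of 14 higher and a median of -0.51 (percentile 4.98 among matched random lists) that turned to 0.13 with a minimum of 100 UMIs; Cd74 was at 0.44 (1.06 as a mean over cells), the costimulator Cd40 at 2.19 and the peptide loader H2-DMa at -1.29. The Toll-like receptor 4 list had 7 genes higher and 10 lower (median -0.10, positive with size factors), with Irak3 at 1.87 and Irak4 at -1.33.

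T cell-like cells of CLP had higher interferon response, cytotoxic and inhibitory receptor genes than those of Sham. Clusters 5 and 11 held most Sham cells and clusters 4, 8, 14 and 15 most CLP cells, with 421 of them in cluster 15. Cxcl10, an interferon-induced chemokine, was at 0.338 CPM in Sham and 70.8 in CLP (7.71; 6.73 without cluster 15), the protease inhibitor Serpina3g at 1.60 and 71.3 (5.48; 4.58 without it), and Ifit3, uncertain because of a near-identical paralog, at 14.5 and 178 (3.61). Dtx1, a Notch regulator, was at 79.8 and 15.1 CPM (-2.41), Clec2d at 187 and 45.9 (-2.02), and Trat1, a T cell receptor adaptor, at 101 and 27.1 (-1.89). All 31 measured type I interferon response genes were higher (median 2.02; Mx1 4.09, Rsad2 3.42), as were all 13 of interferon-gamma (1.70; Iigp1 3.08, Gbp2 2.65). Cytotoxic effectors were higher in 16 of 17 (2.40, but 1.37 without cluster 15 and 1.73 without members that free RNA could supply), with the chemokine Xcl1 at 2.85 (0.87 without cluster 15, 3.49 as a mean over cells) and Fasl, a death ligand, at 2.46 (1.18 without cluster 15). Inhibitory receptors and suppressive factors were higher in 13 of 16 (1.78; Lag3 2.76, Cd274 2.55), while Foxp3, the regulatory T cell factor, was lower (-0.87). Naive state genes were lower in 12 of 14 (-0.52), such as the lymph node homing receptor Ccr7 (-0.83) and the integrin Itga4 (-1.02). Glucocorticoid response genes were higher in 14 of 16 (0.55; Klf9 2.44), although Tsc22d3 was lower (-0.34). The proliferation marker Mki67 was higher (2.15), but by 0.25 with each library clustered alone and 1.02 to 1.20 under 4 other settings. The cell cycle median of 1.21 was 0.10 with each library clustered alone and 0.32 to 0.37 under the same 4.

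B cell-like cells of CLP had higher interferon genes and lower MHC class II genes, and much of their higher activation genes lay in 1 small cluster. Clusters 3 and 12 held most Sham cells, cluster 13 most CLP cells, and cluster 23 held 81 CLP cells. Cxcl10 was at 0.418 CPM in Sham and 105 in CLP (7.98; 4.01 without cluster 23, 5.28 as a mean over cells, 8.62 with the 5% mitochondrial limit), Ifitm1, an antiviral membrane protein, at 2.92 and 295 (6.66; 2.86, 4.14 and 7.65 in the same order), and the cytokine signalling inhibitor Socs3 at 8.85 and 287 (5.02). Fcer2a, the low affinity IgE receptor CD23, was at 296 and 11.6 CPM (-4.68), the lymphotoxin gene Ltb at 1007 and 144 (-2.80), and Vpreb3 at 548 and 80.9 (-2.76). Type I interferon response genes were higher in 27 of 29 (median 1.33; Isg15 3.37, or 1.86 without cluster 23 and 2.62 as a mean over cells, and Zbp1 2.98), and those of interferon-gamma in 12 of 13 (1.54; Gbp2 2.19). MHC class II genes were lower in 12 of 14 (-1.13), including the class II transactivator Ciita (-2.21; -1.59 without cluster 23) and H2-DMb2 (-1.90), though the costimulator Cd86 was higher (1.90). Activation genes were higher in 11 of 13 (1.23, but 0.23 without cluster 23; Egr2 4.83, or 1.16 without it and 5.62 with the 5% limit).

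NK cell-like cells of CLP had higher Gzmb and inhibitory receptor genes and lower trafficking genes than those of Sham. Cluster 20 held most Sham cells and clusters 7 and 24 most CLP cells. Ly6a (Sca-1) was at 2.97 CPM in Sham and 406 in CLP (7.10), the granzyme gene Gzmb at 850 and 4807 (2.5), and Gadd45g, a stress response gene, at 22.99 and 156 (2.77). Abcg1, a cholesterol exporter, was at 65.3 and 4.28 CPM (-3.93; -3.34 as a mean over cells), the desaturase Scd2 at 76.4 and 5.50 (-3.80), and Gstm1 at 58.6 and 8.10 (-2.86). Type I interferon response genes were higher in 26 of 28 (median 1.16; Zbp1 1.96). Inhibitory receptors and suppressive factors were higher in 10 of 13, with a median of 0.94 that was up to 2.04 under other settings. Ctla4 had 1 UMI in Sham against 34.1 CPM in CLP (5.52, 3.03 to 10.83) and Lag3 1 UMI against 30.4 CPM (5.36, 2.86 to 10.67). Il10 was 11.9-fold higher over a floor of 3 counts in Sham. Trafficking receptors were lower in 11 of 17 (-0.91), among them S1pr5, which guides NK cell exit from tissue (-2.09). Glucocorticoid response genes were lower in 12 of 16 (-0.64; Cxcr4 -1.35), with Fkbp5 higher (0.61).

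The median log2 ratio over all measured genes between CLP and Sham was -0.28 in neutrophil-like, -0.18 in monocyte-like, -0.12 in B cell-like, -0.06 in T cell-like and -0.26 in NK cell-like cells. Relative to it, the list medians of neutrophil-like cells were 1.52 for type I interferon, 1.44 for granule genes, 0.92 for oxidative phosphorylation and 0.89 for MHC class I. They were -0.88 for glucocorticoid response and -2.03 for immediate early and dissociation-associated genes. For the inflammatory and Toll-like receptor 4 lists, which were negative before, they were 0.17 and 0.24. In monocyte-like cells they were 4.23 for cell cycle, 2.55 for interferon-gamma, 2.39 for inflammatory, 0.85 for type I interferon, 0.81 for glycolysis, 0.09 for Toll-like receptor 4 (negative before), -0.32 for MHC class II and -2.11 for non-classical genes. In B cell-like cells they were 1.66 for interferon-gamma, 1.45 for type I interferon, 1.35 for activation and -1.02 for MHC class II, and in NK cell-like cells 1.42 for type I interferon, 1.20 for inhibitory receptors, -0.38 for glucocorticoid response and -0.65 for trafficking. Free RNA differed between the libraries: the neutrophil transcript S100a8 was at 32.7 CPM in T cell-like cells of Sham, 1480 in those of CLP and 2460 in those of HDCA+CLP. Malat1, a nuclear long non-coding RNA, and AY036118 differed too, and both were chosen after their values were seen. Malat1 was lower and AY036118 higher in CLP than in Sham in all 5 classes. In neutrophil-like cells Malat1 was at 24300 CPM in Sham and 6460 in CLP.

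**Figure D2:**
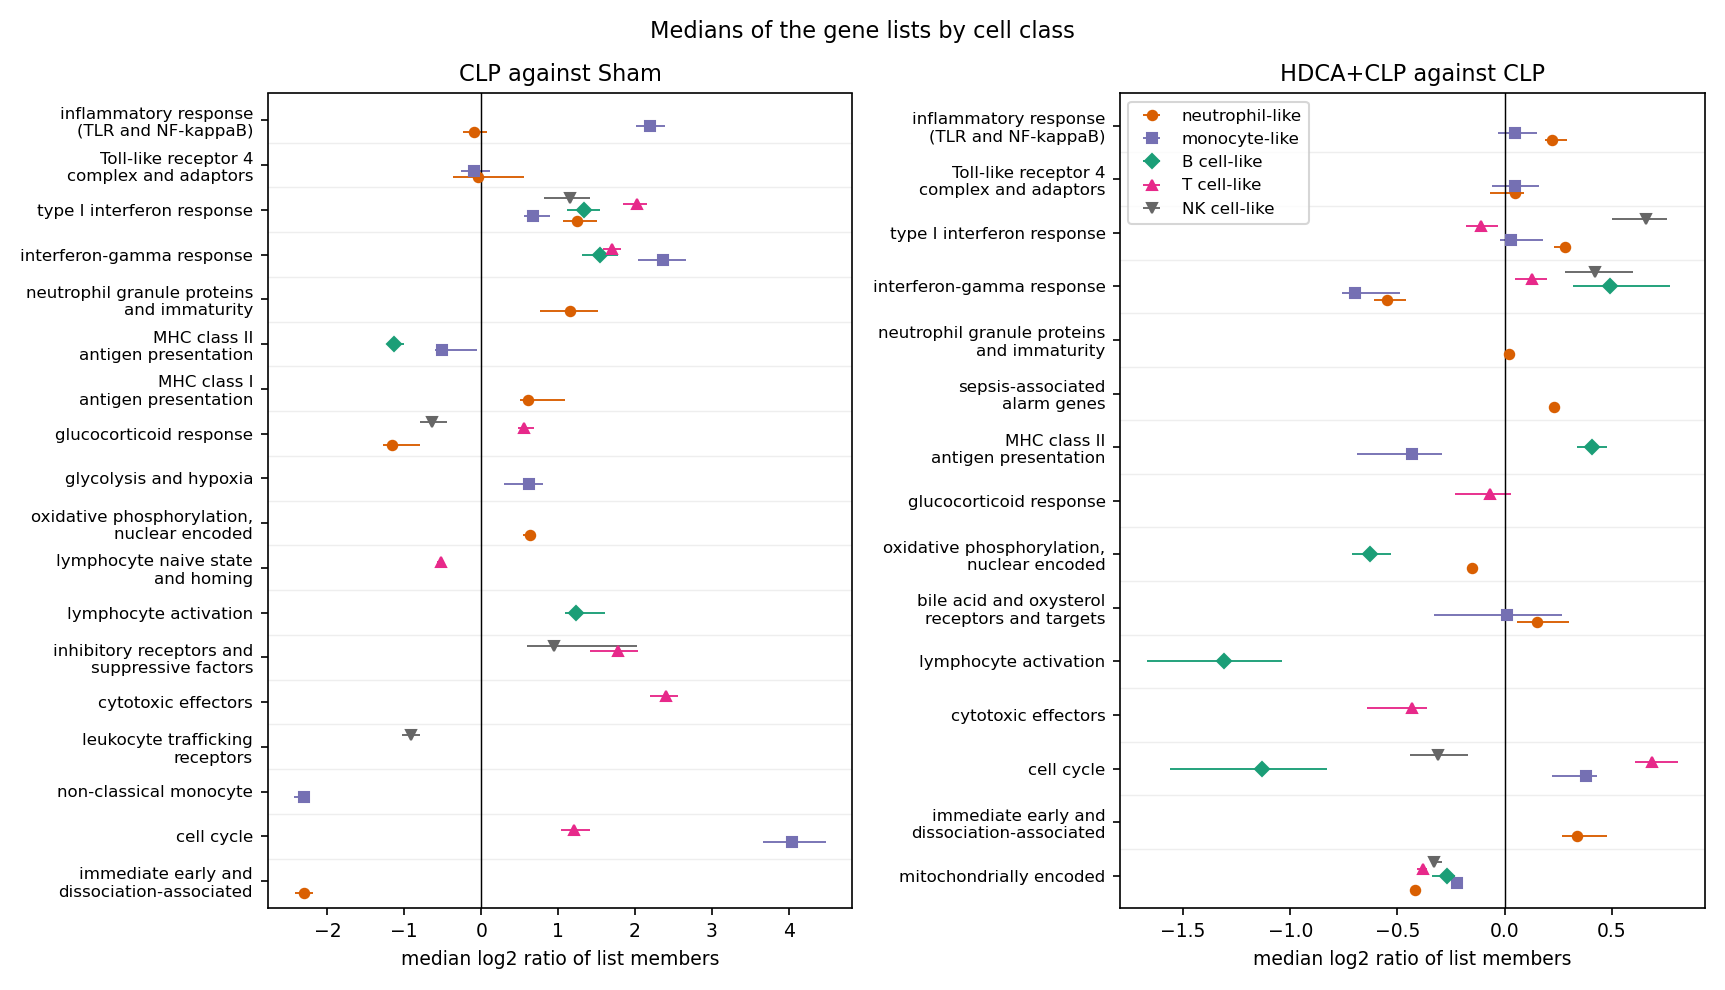
Median log2 ratio of the members of each reported gene list (horizontal axis) by cell class, for CLP against Sham and for HDCA+CLP against CLP, with 95% counting intervals. In CLP against Sham type I interferon response genes had positive medians in all 5 classes. The inflammatory list had a median of -0.10 in neutrophil-like cells, which turned positive with size factors, and of 2.20 in monocyte-like cells.

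Between HDCA+CLP and CLP the neutrophil-like share was higher, and interferon-gamma response genes were lower in neutrophil-like and monocyte-like cells but higher in B cell-like and NK cell-like cells. Neutrophil-like cells were 75.27% (74.45 to 76.08) of HDCA+CLP cells, 1.66-fold the CLP share. Lower shares were found for T cell-like cells (12.95%, 12.32 to 13.60; 2.36-fold lower), monocyte-like cells (2.98%, 2.67 to 3.31; 2.53-fold lower) and NK cell-like cells (5.13%, 4.73 to 5.57; 2.20-fold lower). B cell-like cells were 2.72% (2.42 to 3.04) of HDCA+CLP cells, a log2 ratio of -0.36 (-0.68 to -0.05) that turned to 0.33 with a limit of 5% mitochondrial UMIs per cell. Among cells other than neutrophil-like cells, monocyte-like cells were 13.74% of CLP and 12.04% of HDCA+CLP cells, T cell-like cells 55.82% and 52.37%, and NK cell-like cells 20.63% and 20.76%, while B cell-like cells were higher in HDCA+CLP (11% against 6.40%).

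In neutrophil-like cells an interferon-induced gene and a pair of stefins, which inhibit cysteine proteases, were higher in HDCA+CLP, and interferon-gamma response genes were lower. Ifi27l2a was at 579 CPM in CLP and 1325 in HDCA+CLP (1.20, 1.17 to 1.22). BC100530 was at 34.8 and 81.0 (1.22) and Stfa2 at 29.8 and 67.8 (1.19), 2 near-identical stefins whose counts cannot be assigned with certainty. Mt1 was at 165 and 91.9 CPM (-0.85), Thbs1, the adhesive glycoprotein thrombospondin 1, at 365 and 217 (-0.75), and AY036118, a transcript from the ribosomal RNA region, at 286 and 171 (-0.74). Of 29 inflammatory genes 20 were higher in HDCA+CLP (median 0.22, and 0.06 with clusters weighted as in CLP): Il1b was at 161 and 318 CPM (0.98; 0.38 weighted), the neutrophil attractant Cxcl2 at 1591 and 2815 (0.82) and Cxcl3 at 29.5 and 56.3 (0.93; 0.32 weighted), while Ccl3 was lower (-0.19). The mix of clusters differed: cluster 10, whose 10 highest genes include Cxcl2, Il1b and Cd14, held 199 of 4459 CLP and 839 of 8166 HDCA+CLP neutrophil-like cells. All 13 interferon-gamma response genes were lower (median -0.55), with the immunity GTPases Igtp at -0.72 and Irgm1 at -0.55 and the guanylate-binding Gbp7 at -0.35. Type I interferon response genes were higher in 23 of 31 (0.28; Isg20 0.86, Irf7 0.77), with Stat2 lower (-0.49). Immediate early and dissociation-associated genes were higher in 15 of 19 (0.34, with Egr1 at 1.12 and Fos at 0.81), and cell handling was not tested here either. Sepsis-associated neutrophil genes were higher in 15 of 20 (0.23, with Stfa2l1 at 0.66), while the alarmin S100a8 was lower (-0.13). Granule genes split 11 to 8 with a median of 0.02 that was negative as a mean over cells; Ly6g (0.59) and the granulocyte factor Cebpe (0.50) were higher and Chil3 was lower (-0.33). Nuclear oxidative phosphorylation genes were lower in 30 of 34 (-0.15; Ndufa4 -0.40).

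The receptors through which lipopolysaccharide and bile acids act were examined as genes fixed in advance. In neutrophil-like cells Tlr4, the lipopolysaccharide receptor, was at 27.3 CPM (exact Poisson interval 18.7 to 38.5) in Sham, 15.8 (14.6 to 17.1) in CLP and 18.1 (17.1 to 19.1) in HDCA+CLP. Its partner Ly96 (MD-2) was at 21.3, 13.02 and 15.9 CPM in the same order, and its coreceptor Cd14 at 262.5, 509 and 606. The HDCA+CLP against CLP ratios were 0.19 for Tlr4, 0.29 for Ly96 (0.00 with clusters weighted as in CLP) and 0.25 for Cd14. In monocyte-like cells Tlr4 was at 15.4, 11.2 and 9.37 CPM, Ly96 at 45.6, 40.4 and 32.3, and Cd14 at 80.6, 283 and 330.4, with ratios of -0.26, -0.32 and 0.22 between HDCA+CLP and CLP. The whole Toll-like receptor 4 list had medians of 0.05 in both classes, and these fell to 0 or below when clusters were weighted (neutrophil-like) or size factors used (monocyte-like). Nr1h4, the bile acid receptor FXR, had no UMI in either class, with an exact Poisson upper bound of 0.0565 CPM in HDCA+CLP neutrophil-like cells, and Gpbar1, the bile acid receptor TGR5, had 1 UMI, in those cells. Bile acid and oxysterol receptor and target genes had 6 of 8 higher in neutrophil-like cells (0.15, turning to -0.02 with clusters weighted; S1pr2 0.45), and 5 of 10 higher in monocyte-like cells (0.01, negative with size factors), with the liver X receptor Nr1h3 at -0.59.

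**Figure D3:**
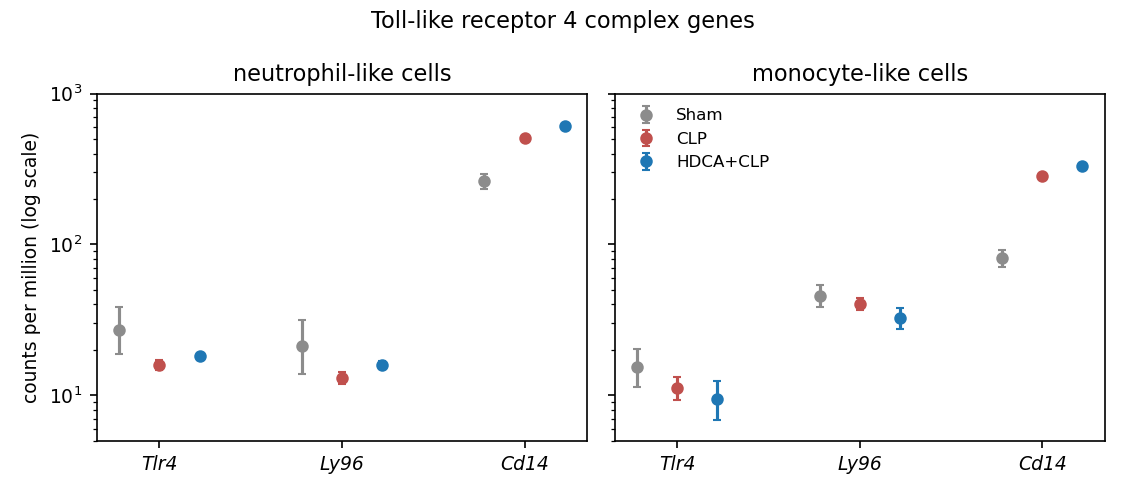
Expression (CPM, log axis) of Tlr4, Ly96 and Cd14 in neutrophil-like and monocyte-like cells of each library, with exact Poisson 95% intervals. Cd14 in neutrophil-like cells was at 262.5 CPM in Sham, 509 in CLP and 606 in HDCA+CLP, while Tlr4 was at 27.3, 15.8 and 18.1.

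In monocyte-like cells, inflammatory genes were divided between HDCA+CLP and CLP, and interferon-gamma response and MHC class II genes were lower in HDCA+CLP. Nos2 was at 14.8 CPM in CLP and 71.5 in HDCA+CLP (2.28, 2.01 to 2.55). Hist1h1b was at 46.9 and 220 CPM (2.23, but 1.20 without doublet removal and -1.04 at a clustering resolution of 2) and Hist1h4d at 14.8 and 61.9 (2.07; 0.59 there, and 1.35 without doublet removal), replication-dependent histones with near-identical paralogs. Spp1 was at 527 and 152 CPM (-1.79), the lipid carrier Apoe at 171 and 58.5 (-1.55; -0.74 as a mean over cells), and AY036118 at 465 and 180.2 (-1.37). Of 30 inflammatory genes 16 were higher (median 0.05, at the percentile 77.74 among matched random lists, and -0.04 at resolution 2): Acod1 was at 119 and 249.5 CPM (1.07) and Il1a at 2.80 and 11.9 (2.08), while Ccl2 was at 655 and 321 (-1.03) and Ccl4 at 388 and 235 (-0.72; -1.74 at resolution 2, -1.33 as a mean over cells). Interferon-gamma response genes were lower in 14 of 15 (median -0.70), including Iigp1 (108 and 52.1 CPM, -1.06), Igtp (-0.88) and Ifi47 (-0.75). MHC class II genes were lower in 10 of 14 (-0.43, and -0.95 without doublet removal), with Cd74 at -0.79 and H2-Ab1 at -0.75. Type I interferon response genes were level (17 of 31 higher, median 0.03, negative with size factors), with Isg20 at 1.00 and Ifi204 at -0.55. Cell cycle genes were higher in 14 of 18 (0.38), and Mki67 was at 0.76 but at 0.08 at resolution 2. There 252 rather than 323 HDCA+CLP cells were named monocyte-like. Retnlg, a neutrophil transcript chosen after its values were seen, was at 73.2 and 709 CPM in monocyte-like cells (3.28; 2.25 without doublet removal, 2.67 at resolution 2).

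**Figure D4:**
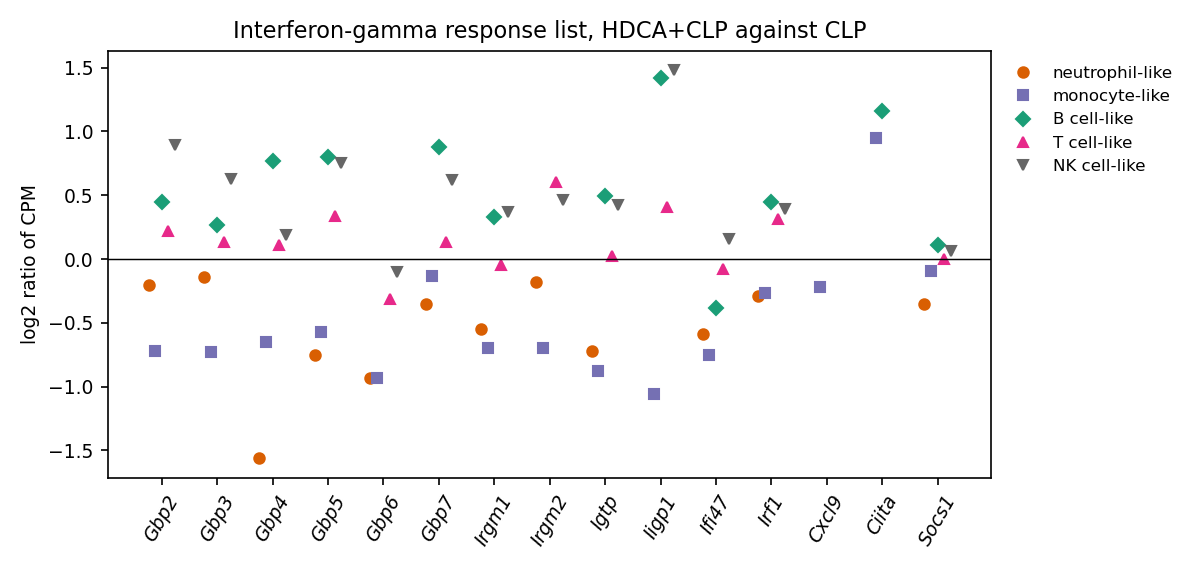
Log2 ratios of CPM, HDCA+CLP against CLP (vertical axis), for each interferon-gamma response gene (horizontal axis), with 1 point per cell class where the gene had enough UMIs. List medians were -0.55 in neutrophil-like, -0.70 in monocyte-like, 0.49 in B cell-like and 0.42 in NK cell-like cells, and 0.13 in T cell-like cells, where the sign turned with size factors.

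In T cell-like cells histone and proliferation genes had ratios that depended on the setting, and cytotoxic genes were lower in HDCA+CLP, less so with clusters weighted as in CLP. That weighting also left out cluster 15, which held 421 CLP and 23 HDCA+CLP cells of its 462. Hist1h1b was at 66.8 CPM in CLP and 170 in HDCA+CLP (1.35; from -0.41 to 0.76 under 7 other settings), the replication factor gene Pclaf at 33.3 and 79.2 (1.25; 0.66 weighted) and Mki67 at 27.2 and 59.3 (1.12), and with each library clustered alone these turned to -2.49, -4.32 and -0.89. Bcl2a1b, a survival gene with near-identical paralogs, was at 115 and 36.4 CPM (-1.66; -0.18 weighted, -2.57 clustered alone), Serpina3g at 71.3 and 24.8 (-1.53; -0.58 weighted) and AY036118 at 708.5 and 289.5 (-1.29). The median over all genes was 0.14 in this class. Relative to it, cell cycle genes had a median of 0.55 (18 of 18 higher; 0.69 before, turning to -1.03 with each library clustered alone), cytotoxic effectors -0.57 (14 of 17 lower; -0.43 before, which became -0.13 weighted and -1.21 with each library clustered alone), and glucocorticoid response genes -0.21 (9 of 17 lower; -0.07 before). Xcl1 was at -2.54, Fasl at -1.18 and Zbtb16, a factor of innate-like T cells, at -2.36, which weighted were -0.18, -0.07 and -0.74, while Xcl1 was -3.96 with the 5% mitochondrial limit; Fkbp5, a glucocorticoid target, was at 0.31. Type I interferon response genes stood at -0.25 (18 of 31 lower; -0.11 before, turning to 0.10 weighted; Usp18 0.62), and those of interferon-gamma at -0.02 (9 of 13 higher; 0.13 before; Iigp1 0.41, Irf1 0.31).

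In B cell-like cells the immediate early genes Fos (51.6 and 244.9 CPM, 2.25, or 1.64 in cluster 13 alone), Fosb (31.3 and 126.5, 2.02, or 4.06 with the 5% mitochondrial limit) and Dusp1 (139 and 353, 1.35) were higher in HDCA+CLP. Cell handling was not tested as a source of these differences. Bcl2a1d (171 and 9.29 CPM, -4.21), the fatty acid carrier Fabp5 (91.8 and 4.64, -4.30) and Cxcl10 (105 and 6.96, -3.92) were lower, and in cluster 13 alone they were -0.75, -0.68 and -0.14. Fabp5 ran from -5.27 to -3.49 and Cxcl10 from -5.02 to -1.15 under other settings. Cluster 13 alone leaves out cluster 23, which had 81 CLP cells out of 93. Interferon-gamma response genes were higher in 12 of 13 (median 0.49; Iigp1 1.42, or 0.71 with the 5% limit, Ciita 1.16, Gbp7 0.88) and MHC class II genes in 11 of 13 (0.41; H2-Ab1 0.44). Nuclear oxidative phosphorylation genes were lower in 32 of 34 (-0.63; Uqcrq -1.46 and Cox7b -1.30, or -0.43 and -0.63 in cluster 13 alone). Activation genes were lower in 11 of 12 (-1.31, and -0.22 in cluster 13 alone; the plasma cell factor Irf4 -2.23, or -0.88 in cluster 13 alone and -3.97 with the 5% limit) although Cd69 was higher (0.61), and cell cycle genes in 9 of 10 (-1.13, -0.27 as a mean over cells and -0.03 in cluster 13 alone).

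In NK cell-like cells Dgat1, which makes triglycerides, was at 60.6 CPM in CLP and 142 in HDCA+CLP (1.22), Pcyt1a, of phosphatidylcholine synthesis, at 21.2 and 51.1 (1.27), and P2ry10, a lysolipid receptor, at 58.8 and 117.7 (1.00). Xcl1 was at 61.6 and 21.5 CPM (-1.52; -2.12 to -2.29 under 4 other settings), AY036118 at 647.5 and 301.5 (-1.10), and Hist1h2ap, a histone with near-identical paralogs, at 451 and 227.5 (-0.99; down to -7.33 under other settings). All 30 type I interferon response genes were higher (median 0.66; Usp18 1.07), as were 12 of 13 of interferon-gamma (0.42; Gbp2 0.89, Gbp5 0.75). Cell cycle genes were lower in 14 of 18 (-0.31, and -3.03 with each library clustered alone; Cdk1 -1.27, or -0.57 without doublet removal and -4.40 clustered alone).

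Some transcripts differed in the same direction in all 5 classes between HDCA+CLP and CLP. Mitochondrially encoded transcripts had medians of -0.42 in neutrophil-like, -0.22 in monocyte-like, -0.27 in B cell-like, -0.38 in T cell-like (mt-Co3 -0.53, mt-Atp6 -0.50) and -0.33 in NK cell-like cells, and the T cell-like median was -0.53 relative to all genes. The nuclear long non-coding RNA Malat1, chosen after its values were seen like AY036118 outside the lists above, was higher in all 5, by log2 ratios of 0.47, 0.42, 0.90, 0.49 and 0.42 in the same order, and AY036118 was lower in all 5, from -0.74 in neutrophil-like to -1.37 in monocyte-like cells. Of the 3 libraries, CLP had the lowest Malat1 and the highest AY036118 in each class. In NK cell-like cells Malat1 was at 25600 CPM in Sham, 14300 in CLP and 19200 in HDCA+CLP. In T cell-like cells AY036118 was at 333, 708 and 289 CPM. With 1 library per group, a difference between libraries and one of treatment cannot be separated here. Neutrophil transcripts in lymphocytes were higher in HDCA+CLP, where S100a8 was at 4910 CPM in B cell-like cells against 1990 in CLP. Other transcripts foreign to a class differed too: the globin Hbb-bs was at 0.68 CPM in B cell-like cells of CLP and 602 in those of HDCA+CLP, and Igkc, an immunoglobulin gene, at 9.46 and 719 in T cell-like cells. Neither was a background shared by all classes of HDCA+CLP. There Hbb-bs was at 2.61 CPM in T cell-like cells, and Igkc at 0.695 in NK cell-like and 1.53 in neutrophil-like cells. Whether a few cells carried them was not tested.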

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

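For the share of neutrophil-like cells, the 3 tests were chosen after the result was seen. For the other tests the predictions were written before the tests, but the patterns they address came from these same data. The weighting of clusters that some of them use was added after the data were seen. Cell classes with medians of at least 0.3 in size, whose counting intervals left out 0, moved in opposite directions in 4 gene lists, and the difference between the classes was not tested in any of them. Glucocorticoid response genes in CLP against Sham had median log2 ratios of -1.16 in neutrophil-like, -0.64 in NK cell-like and 0.55 in T cell-like cells. In HDCA+CLP against CLP, MHC class II genes had medians of -0.43 in monocyte-like and 0.41 in B cell-like cells. Cell cycle genes in the same comparison were at 0.38 in monocyte-like, 0.69 in T cell-like, -0.31 in NK cell-like and -1.13 in B cell-like cells, but at -1.03 in T cell-like cells with each library clustered alone, and at -0.03 in cluster 13 alone and -0.27 as a mean over cells in B cell-like cells. Interferon-gamma response genes were at -0.55 in neutrophil-like, -0.70 in monocyte-like, 0.49 in B cell-like and 0.42 in NK cell-like cells.

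The interferon-gamma response list was lower in both myeloid classes of HDCA+CLP. A different mix of neutrophil-like clusters is argued against, since the median was -0.70 with the clusters weighted as in CLP. Free RNA of T and NK cells, a larger share of the CLP library, is argued against too. The pooled T and NK cell profile was taken off in the amount that Gzma allows. In CLP Gzma was at 23900 CPM in NK cell-like and 318 in T cell-like cells, so free RNA of T cells alone was hardly tested. In CLP that was 0.309% of the UMIs of neutrophil-like cells and 0.889% of those of monocyte-like cells. The median was then -0.54 in neutrophil-like and -0.69 in monocyte-like cells. What stays open is a difference between the 2 libraries or animals other than treatment, and an effect of HDCA, which was not tested. Free RNA of other classes was not tested either, such as that of monocyte-like cells, which were 7.52% of CLP and 2.98% of HDCA+CLP cells. Nor was a different mix of cells within the monocyte-like class. In B cell-like and NK cell-like cells of HDCA+CLP the list was higher.

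The neutrophil-like share was higher in HDCA+CLP than in CLP. Cell filters, doublet calls and clustering are argued against as its whole cause, since the lowest log2 ratio over the 6 alternatives was 0.58. A different yield of neutrophils alone would leave the shares among other cells level. B cell-like cells argue against it, at 0.78, but T cell-like, NK cell-like and monocyte-like cells were close to level, with -0.19 the farthest from 0, so a different neutrophil yield may account for those 3 classes. A higher number of neutrophils in blood under HDCA predicts the same and stays open, untested.

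Mitochondrially encoded transcripts were lower in all 5 classes of HDCA+CLP than of CLP. In T cell-like cells, the class these tests cover, the median was -0.40 with a limit of 20% mitochondrial UMIs per cell in place of 10%. The 10% limit removed 542 CLP and 166 HDCA+CLP barcodes over all classes. Raising it could therefore hardly have shrunk the difference, and the test says little about the limit as a cause. A different mix of T cell-like clusters is argued against, at -0.33 with clusters weighted as in CLP and cluster 15 left out. A difference between the libraries in preparation and an effect of HDCA on all blood cells both stay open, since 1 library per group confounds them and neither was tested.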

How the results depend on the processing

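Weighting the clusters as in CLP, leaving out clusters mostly of CLP and leaving out list members under the free RNA limit were the alternatives chosen after the data were seen; the others were fixed before. Of 1860 values of 215 gene results 1848 kept their sign, and 114 moved by more than 1.5-fold. Many of these genes were named for large differences in the same data, so a kept sign was likely from the start. Of 694 values of 65 list results 660 kept their sign, and 25 moved by more than 1.5-fold. These 65 were a selection of the pairs computed, so the counts describe only them. Of 68 values of 10 shares 64 kept their sign, and 10 moved by more than 1.5-fold. Where results moved or reversed, the cause was not tested unless given.

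With a limit of 5% mitochondrial UMIs per cell, log2 ratios of shares in CLP against Sham were 3.06 (neutrophil-like), 0.39 (monocyte-like), -4.24 (B cell-like), -1.03 (T cell-like) and 0.87 (NK cell-like). In HDCA+CLP against CLP they were 0.58 (neutrophil-like), -1.01 (T cell-like) and, reversed, 0.33 (B cell-like). The monocyte-like ratio of CLP against Sham was 0.46 at resolution 2, and the T cell-like one of HDCA+CLP against CLP -1.37 with each library clustered alone. Among cells other than neutrophil-like cells, a smaller denominator by construction, CLP against Sham gave 1.57 for monocyte-like, -2.72 for B cell-like, 2.21 for NK cell-like and, reversed, 0.21 for T cell-like cells. HDCA+CLP against CLP gave -0.19 for monocyte-like, -0.09 for T cell-like and, reversed, 0.78 for B cell-like and 0.01 for NK cell-like cells.

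Among list medians of CLP against Sham, the inflammatory list in neutrophil-like cells was 0.09 with size factors and 0.14 as a mean over cells, and in monocyte-like cells 2.47 both with a minimum of 100 UMIs and without members under the free RNA limit. The MHC class II list in monocyte-like cells was -0.64 without doublet removal, -0.04 as a mean over cells and 0.13 with a minimum of 100 UMIs, where fewer members were left. The glucocorticoid list in T cell-like cells was 0.38 without members under the free RNA limit and 0.46 without cluster 15, which is mostly of CLP; without it Zbtb16 in these cells was reversed at -0.15, so its higher level in CLP lay in that cluster.

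For HDCA+CLP against CLP, the inflammatory list in neutrophil-like cells was 0.06 with clusters weighted and 0.32 without members under the free RNA limit, and in monocyte-like cells -0.04 at resolution 2. In monocyte-like cells the type I interferon list was -0.03 with the 5% limit, and the MHC class II list -0.95 without doublet removal. Reversed medians were -0.02 for bile acid genes in neutrophil-like cells and 0.10 for type I interferon in T cell-like cells with clusters weighted (cluster 15 left out), -0.01 for interferon-gamma in T cell-like cells with size factors, and -1.03 for cell cycle genes in T cell-like cells with each library clustered alone. In that last setting Hist1h1b, Pclaf and Mki67 in T cell-like cells were reversed at -2.49, -4.32 and -0.89. Hist1h1b was also reversed at -0.41 in T cell-like cells without doublet removal and at -1.04 in monocyte-like cells at resolution 2.

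No paired analysis was possible because each group has 1 library. Depth limits the Sham neutrophil-like cells, with 1173438 UMIs against 38336417 in CLP, and the B cell-like cells of HDCA+CLP, with 861538, and no alternative can show the variation between animals.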

Other observations

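All genes in this part were chosen after their values were seen. Ifng, the interferon-gamma gene, was at 1.64 CPM in T cell-like cells of Sham, 21.0 in CLP and 8.15 in HDCA+CLP. The log2 ratio of CLP against Sham was 3.68 (3.17 to 4.23), or 2.42 without cluster 15 and 4.27 with a limit of 5% mitochondrial UMIs, and the log2 ratio of HDCA+CLP against CLP was -1.37 (-1.81 to -0.95), or -0.33 with clusters weighted as in CLP and cluster 15 left out, -2.25 as a mean over cells and -3.61 with each library clustered alone. In NK cell-like cells it was at 115, 214 and 134 CPM (-0.67, -0.84 to -0.51, between HDCA+CLP and CLP).

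Il10, an anti-inflammatory cytokine gene, was at 14.8 CPM in neutrophil-like cells of CLP and 3.76 in those of HDCA+CLP (-1.98, -2.20 to -1.76). Genes of early myeloid granules were higher in monocyte-like cells of CLP than of Sham: Elane had 4 UMIs in Sham against 100.1 CPM in CLP (6.28, 4.92 to 8.16; 5.37 at a clustering resolution of 2), Mpo 2 UMIs against 45.1 CPM (6.13, 4.27 to 9.18; from 2.90 to 7.14 under other settings), and Prtn3 was at 38.6 and 269.7 CPM (2.81; 1.81 at resolution 2). Fewer CLP cells were named monocyte-like at resolution 2 (607 rather than 741), so part of these 3 differences lay in cells without a stable class name. Ifngr1, a subunit of the interferon-gamma receptor, was at 707 CPM in monocyte-like cells of Sham and 165 in those of CLP (-2.10, -2.19 to -2.01).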
